A study of Mus musculus with 18 samples.

How the data were processed

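RNA was measured by sequencing in 18 libraries of the mouse embryonic stem cell line ES-E14TG2a. The labels give cells named Ctrlv2, Arf-B and Arf-C, each at day 0 and at day 8 of a differentiation protocol, with 3 replicates per group, which makes 6 groups. Per the labels, polyadenylated RNA was taken from Trizol extracts, activin A (20 ng/mL) with Matrigel was given from day 0, and retinoic acid (written there as 5 μM/ml, a unit left as it stands) with FGF10 (10 ng/mL) from day 4 to day 8. The series title names p19Arf and the pancreatic lineage. The genotype label is wild type for every library, Arf-B and Arf-C included, and how the Arf-B and Arf-C cells were made is not given in the sources used here. Replicates are numbered 1 to 3, without a statement that they are separate cultures, so the p-values below measure only the spread between these samples.

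The deposited table holds FPKM values (fragments per kilobase of gene length and library size) for 54532 genes in each library, with coordinates and gene lengths. The authors' processing notes name HISAT2, featureCounts, DESeq2 and the mm10 assembly. Each value times its gene length is a whole multiple of a step that is fixed within a library. That returned read counts for all 413772 values above 0, the largest deviation from a whole number being 4.8e-05 reads (tolerance 0.001). The library size implied by that step lies within 0.79% of a size from median-ratio factors. Reads on genes ranged from 10432590 to 33311220 per library (ratio 3.19). The means per group were 29917985 (Ctrlv2), 28379571 (Arf-B) and 27179467 (Arf-C) at day 0, and 12502136, 19967324 and 15247361 at day 8. At these depths 3 reads on a gene of 1 kilobase equal 0.093 to 0.282 FPKM, depending on the library. Gene positions were compared with GENCODE vM21: 53585 of the 54532 genes (98.26%) have the same start, end and strand.

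Tests were made with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), and figures with matplotlib 3.10.9 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6). Values were taken as log2(FPKM + 1), and genes with at least 0.5 FPKM in at least 3 libraries were tested (17200). A linear model with 1 coefficient per group over all 18 libraries was followed by empirical Bayes moderation with a trend and robust settings. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p below 0.05. The comparisons were day 8 against day 0 in each line, each Arf line against Ctrlv2 at each day, Arf-B against Arf-C at each day, and the difference between the day responses of each Arf line and of Ctrlv2. Genes called against Ctrlv2 with the same sign in both Arf lines were counted per day. Because both comparisons share their 3 Ctrlv2 libraries, that count is set beside the overlap of independent calls and beside 100 simulations of unchanged lines. These choices, 45 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison; the correlation estimated from the data is the alternative. Chromosome medians used genes with a mean of at least 1 FPKM, each centred on its own mean, tested with limma over chromosomes and the 4 comparisons with Ctrlv2. Values beside a gene are means ± SD of FPKM with n = 3, and log2 fold changes come with the standard error of the fit.

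Genes were named as follows. Cdkn2a, Cdkn2b, Trp53, Mdm2, Cdkn1a and Npm1 are named in every comparison. Others had to be called, carry a symbol that is not a predicted or numbered one, reach a mean of 5 FPKM in the higher group, and have all 3 libraries of one group above all 3 of the other. Among these, the 10 largest rises and falls were taken for the day response of Ctrlv2. For the Arf lines against Ctrlv2 the choice was the 8 largest per direction shared by both lines, ranked by the smaller change, and the 3 largest per direction called in a single line. For the difference in day response 5 per direction called in both lines were taken, without the demand on separation, and 3 per direction between the Arf lines. Of a described list up to 4 called members were taken, or the 2 most abundant where none was called. The rule takes 368 genes, of which the text reports a part. Genes outside this rule, chosen after their values were seen, are Pdx1, Casd1, Ppp1r9a, Jak1, Leprot, Ak4, Ssbp3, Uty, Eif2s3y, Tdgf1-ps1 and Gm46332. Hsd17b14, Laptm5 and Triml1 were also picked after their values were seen, as examples that lie low.

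The procedure was tested on simulated data, with 200 changed genes per comparison. It recovered 31% to 73.7% of changes of 1.5-fold and 70.7% to 92% of changes of 2-fold, and 1.87% to 11.2% of its calls were unchanged genes, the most for Arf-C against Ctrlv2 at day 8. Alternatives named in advance were a pseudocount of 0.1, no filter, a filter at a mean of 1 FPKM, median-ratio scaling, scaling to the same sum (TPM), a fit of the compared groups alone, an absolute log2 fold change of at least 1, the replicate number as a block, and each library left out in turn. For lists they were the estimated correlation, the pseudocount, the filter, median-ratio scaling and the block; for chromosomes, a mean of at least 10 FPKM and median-ratio scaling. Chosen after seeing the data were limma-voom on the recovered reads, reads thinned to the smallest library, and a fit without the genes of 2 chromosome segments. Those segments come from windows of 5 Mb, also chosen after seeing the data: at least 8 genes with a mean of at least 3 FPKM, a median log2 ratio (pseudocount 0.1) beyond 0.3 in size with the same sign in all 4 comparisons, and an adjusted permutation p from 10000 random gene sets below 0.05 in all 4. Called windows that follow each other among those with enough genes form a segment, so the one on chromosome 2 spans a window that was not tested. Raw reads and splice forms were not analysed here.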

Results

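Cdkn2a, the gene that encodes p19Arf and p16Ink4a, was lowly expressed at day 0 and rose in all 3 lines by day 8. In Ctrlv2 cells it went from 2.72 ± 0.752 to 32.9 ± 1.22 FPKM (log2 fold change 3.21, SE 0.111, adjusted p = 5.62e-13). In Arf-B cells it went from 1.99 ± 0.269 to 42.7 ± 2.33, and in Arf-C cells from 2.29 ± 0.0982 to 44.1 ± 1.96. At day 8 both Arf lines lay above Ctrlv2, with log2 fold changes of 0.36 (adjusted p = 0.0202) and 0.41 (0.0101). All 3 libraries of each were higher, but in Arf-B the call rests on single libraries: it was lost without replicate 2 of Ctrlv2 (adjusted p = 0.0612), replicate 1 of Arf-B (0.0689) or replicate 2 of Arf-B (0.0561). With reads thinned to the smallest library neither was called (adjusted p = 0.209 and 0.115). At day 0 Arf-C was not separated from Ctrlv2 (log2 -0.16, adjusted p = 0.278), except without replicate 2 of Ctrlv2 (adjusted p = 0.00339). Arf-B was lower by the test (log2 -0.30, adjusted p = 0.0424). That call was lost without replicate 1 or 3 of Ctrlv2 (adjusted p = 0.14 and 0.229) or replicate 1 or 2 of Arf-B (0.175 and 0.0529), and 1 of the 3 Ctrlv2 libraries (1.89 FPKM) lay inside the range of Arf-B (1.68 to 2.15). Every Arf library held Cdkn2a reads, from 55 to 79 at day 0 and from 807 to 1270 at day 8. These are gene-level values. Its annotated transcripts have separate first exons, at 89281986 to 89282192 and at 89294334 to 89294653 on chromosome 4, and share exon 2, so the table does not tell p19Arf from p16Ink4a transcripts.

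Mdm2, which encodes the ubiquitin ligase that p19Arf inhibits, was higher in both Arf lines at day 0. It was at 31.3 ± 3.98 and 31.2 ± 1.69 against 23.4 ± 0.785 FPKM (log2 0.40 and 0.40, adjusted p = 0.00162 and 0.00139). At day 8 it was lower in both, at 42.1 ± 0.947 and 41.1 ± 4.2 against 58.8 ± 3.52 (log2 -0.47 and -0.51). Cdkn1a, the p21 gene and a direct target of Trp53, was not called at day 0. It was lower at day 8, at 26.6 ± 1.67 and 25.1 ± 3.37 against 38.7 ± 3.08 FPKM (log2 -0.52 and -0.61, adjusted p = 0.00484 and 0.00152). Trp53 itself fell in Ctrlv2 from 129.5 ± 10.9 to 41.2 ± 2.85 FPKM. It was lower in both Arf lines at day 0 (log2 -0.26 and -0.29). The Arf-B call at day 0 was lost without replicate 1 or 3 of Ctrlv2 (adjusted p = 0.0514 and 0.0511) or replicate 1 of Arf-B (0.0533). At day 8 Trp53 was higher in Arf-B (log2 0.32, adjusted p = 0.00416), while Arf-C missed the threshold (log2 0.14, adjusted p = 0.173). Npm1, whose product binds p19Arf in the nucleolus, was higher in Arf-B at day 0 (1106 ± 121 against 854 ± 114 FPKM, log2 0.38, adjusted p = 0.0102), but not without replicate 1 of Ctrlv2 (adjusted p = 0.0614). Arf-C missed the threshold (1029 ± 128, adjusted p = 0.0507) and passed it without replicate 2 of Ctrlv2 (0.0128) or replicate 1 of Arf-C (0.0115). At day 8 it was called in neither line. In Ctrlv2 Mdm2 and Cdkn1a rose by day 8 (log2 1.29 and 1.78) and Npm1 fell (log2 -0.32, adjusted p = 0.0131), the last not without replicate 2 at day 0 (0.078) or replicate 3 at day 8 (0.0551). Cdkn2b, the neighbour of Cdkn2a, rose in Ctrlv2 from 0.471 ± 0.183 to 4.7 ± 1.21 FPKM and was not called between lines at either day (adjusted p of at least 0.251).

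**Figure D1:**
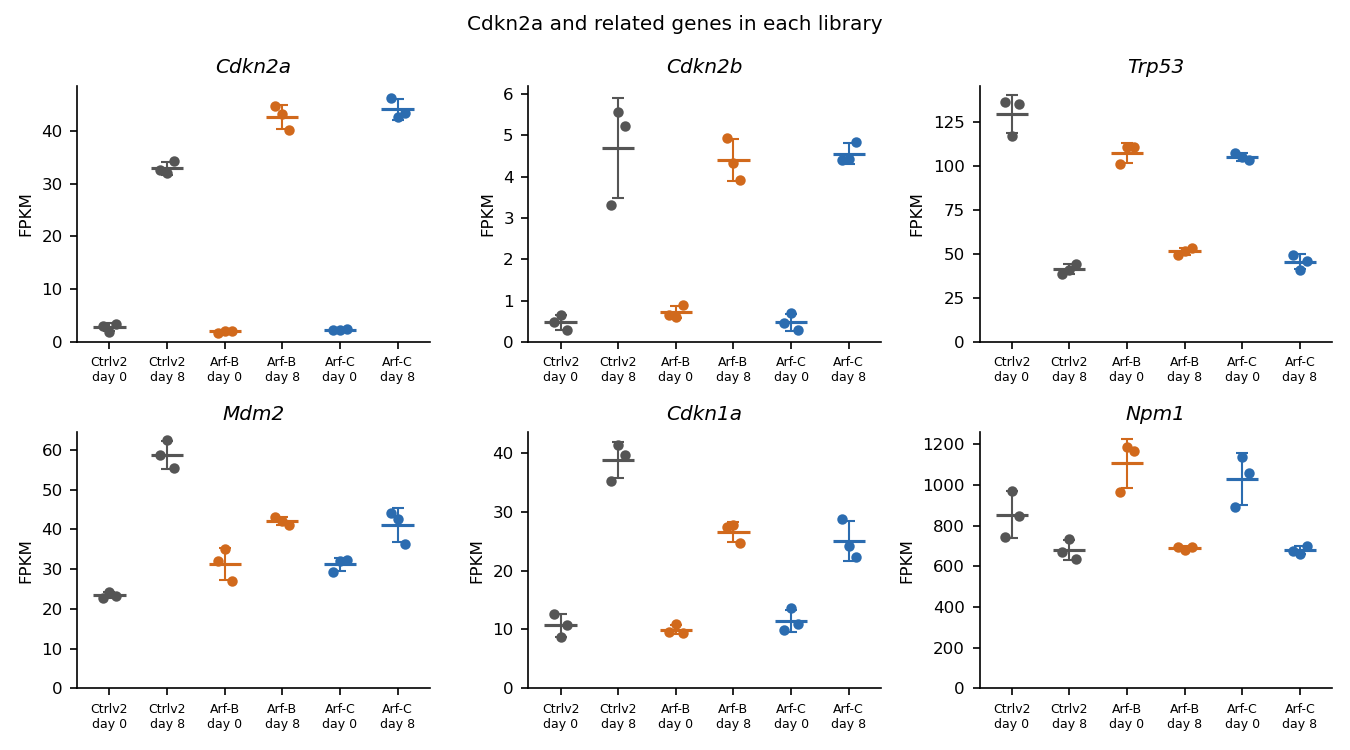
FPKM of Cdkn2a, Cdkn2b, Trp53, Mdm2, Cdkn1a and Npm1 in the 6 groups (linear axes from 0), with 1 point per library, a line at the mean of 3 and error bars of 1 SD. Cdkn2a rises in all 3 lines by day 8, to a mean of 32.9 in Ctrlv2, 42.7 in Arf-B and 44.1 in Arf-C.

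Over the 8 days many transcripts changed in Ctrlv2 cells. Nanog fell from 262 ± 12.4 to 0.537 ± 0.478 FPKM (log2 fold change -7.47, SE 0.285, adjusted p = 4.42e-12). Pou5f1, which encodes the core factor Oct4, fell from 657 ± 46 to 3.53 ± 0.57 (log2 -7.19). Nr0b1, another factor of the naive state, fell from 236 ± 8.78 to 0.277 ± 0.253 (log2 -7.56). The other large falls were Txnip, Sept1, Tdgf1, Tcl1, Tdh (in a segment of chromosome 14 described last), Fgf4 and Mymx, with log2 fold changes from -7.35 (Txnip) to -5.92 (Mymx). Cyp26a1, which encodes the enzyme that clears retinoic acid, rose from 0.135 ± 0.0835 to 566 ± 32.4 FPKM (log2 8.96, SE 0.096, adjusted p = 2.53e-18). Crabp2, for a retinoic acid binding protein, went from 0.874 ± 0.435 to 401 ± 30.1 FPKM. Cyp26b1, Pmp22, Cyr61, Gas1, Krt18, Car4 and Rec8 were also among the 10 largest rises, at log2 5.12 (Rec8) to 6.93 (Pmp22). As the naming rule demands, in each of these genes the 3 libraries of one day lay above the 3 of the other. Of 17200 genes 5838 rose and 5914 fell, 1816 and 1690 of them by at least 2-fold.

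Among the lists, all 15 naive pluripotency genes fell in Ctrlv2 (15 adjusted over the list alone, median log2 -4.73, adjusted p = 4.57e-10, and 0.129 with an estimated correlation). Of core pluripotency genes 10 of 11 fell (10 over the list alone, median -3.37, adjusted p = 4.37e-06, 0.128 estimated). Of 15 genes of the retinoic acid response 13 rose (13 over the list alone, median 4.16, adjusted p = 1.04e-09, 0.0304 estimated). All 23 Hox genes rose (23 over the list alone, median 2.87, adjusted p = 4.05e-13, 0.0392 estimated). Among them Hoxa5 was at 32.5 ± 3.9, Hoxb4 at 32.4 ± 2.52 and Hoxb8 at 17.7 ± 2.23 FPKM on day 8. Imprinted genes rose in 18 of 21 cases and fell in 2 (19 and 2 over the list alone, median 1.43, adjusted p = 2.75e-06, 0.0275 estimated). The largest were Peg3 (1.57 ± 0.287 to 57.6 ± 6.11 FPKM), Peg10, H19 and Igf2. Cell cycle and E2F targets fell in 24 of 27 cases and rose in 2 (the same counts over the list alone, median -1.01, adjusted p = 2.62e-08, 0.0465 estimated). Trophoblast genes rose in 7 of 9 (7 over the list alone, median 0.94, adjusted p = 0.00369, 0.0465 estimated). Those 5 lists (retinoic acid, Hox, imprinted, cell cycle, trophoblast) are the ones that hold with an estimated correlation, of 20 called with the preset one. Primitive and parietal endoderm genes rose in 13 of 15 and fell in 1 (same over the list alone, median 2.61, adjusted p = 2.75e-06, 0.128 estimated). Col4a1 went from 4.0 ± 0.264 to 72.9 ± 11.8 and Lamb1 from 6.26 ± 0.173 to 62.4 ± 6.86 FPKM.

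Among definitive endoderm genes of Ctrlv2, Gata4, in the chromosome 14 segment, rose from 1.72 ± 0.282 to 25.1 ± 1.69 FPKM, and Gata6 from 0.139 ± 0.0168 to 6.47 ± 0.814. Foxa2 rose from 0.0373 ± 0.0394 to 3.91 ± 0.785 and Foxa1 from 0.127 ± 0.0331 to 3.62 ± 0.805. Of 11 tested 6 rose and 5 fell (6 and 5 over the list alone), and the list was not called (median log2 0.77, adjusted p = 0.15). The pancreatic progenitor list, with 6 of 13 genes tested, had 5 rises and 1 fall (same over the list alone, median 1.33, adjusted p = 0.0354, 0.128 estimated). Dlk1 rose from 0.315 ± 0.0328 to 13.6 ± 2.44 FPKM, Prox1, a regulator of foregut endoderm, from 0.0213 ± 0.00906 to 2.89 ± 0.241, and Sox9 from 0.00319 ± 0.00553 to 1.92 ± 0.272. Posterior foregut and gut tube genes rose in 8 of 10 and fell in 2 (same over the list alone, median 1.08, adjusted p = 0.0267, 0.127 estimated). Meis2, in a segment of chromosome 2, was at 17.2 ± 1.5 FPKM on day 8. Pdx1, the pancreas master regulator, was too low to be tested, at 0.137 ± 0.043 FPKM in Ctrlv2, 0.506 ± 0.312 in Arf-B and 0.363 ± 0.0875 in Arf-C at day 8.

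**Figure D2:**
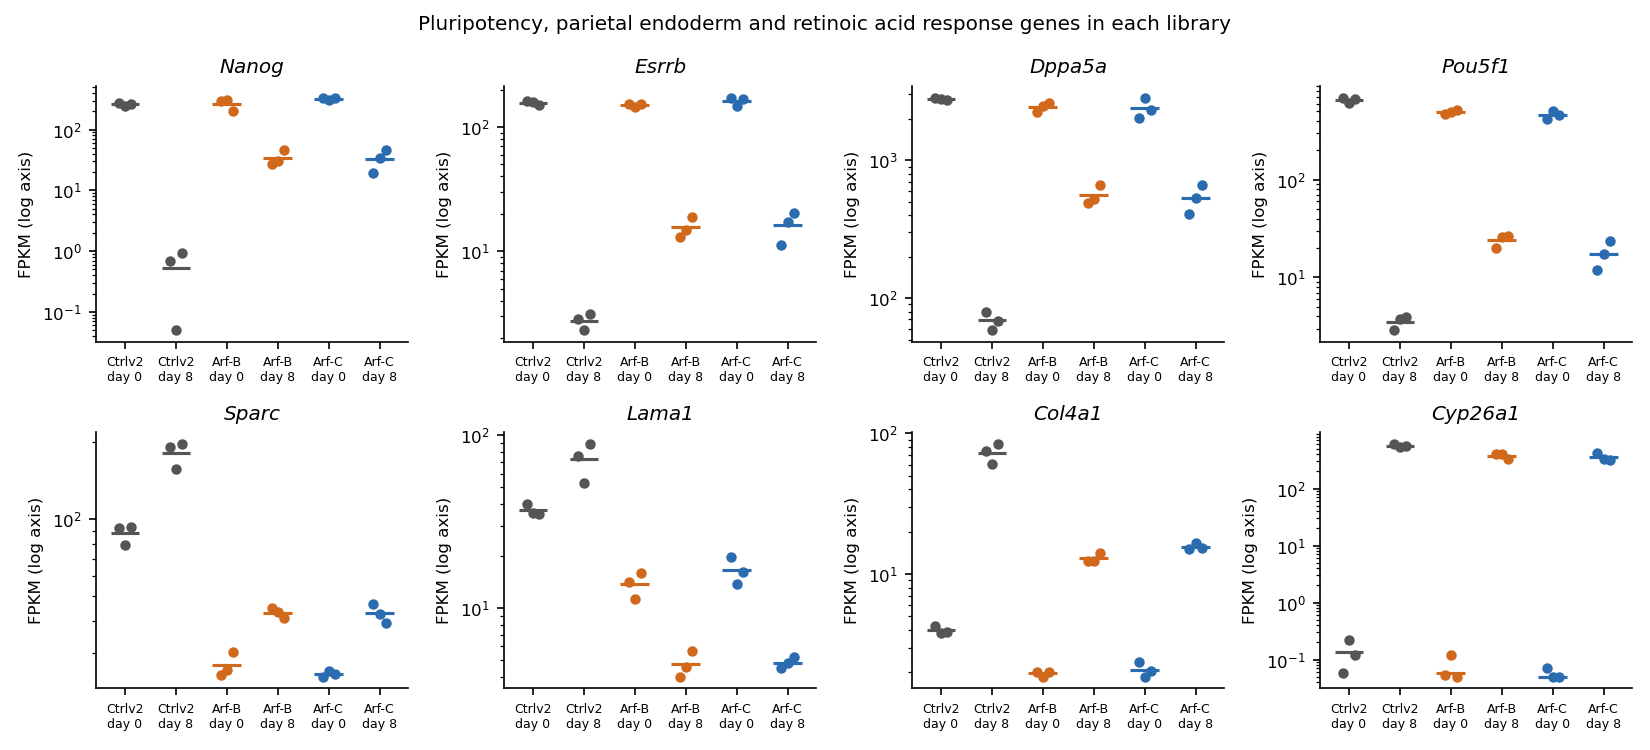
FPKM (log axis, values under 0.05 drawn at 0.05) of Nanog, Esrrb, Dppa5a, Pou5f1, Sparc, Lama1, Col4a1 and Cyp26a1 in the 6 groups, with 1 point per library and a line at the mean of 3. Nanog is at a mean of 0.537 FPKM in Ctrlv2 at day 8 against 34.5 in Arf-B and 32.9 in Arf-C.

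Both Arf lines also lost naive and gained retinoic acid and Hox transcripts by day 8. All 15 naive genes fell in each line (15 over the list alone), by a median log2 of -3.07 in Arf-B and -3.28 in Arf-C (adjusted p = 6.59e-09 and 3.12e-09, 0.164 and 0.159 with an estimated correlation). All 15 retinoic acid genes rose in each (15 over the list alone, medians 4.96 and 5.18, adjusted p = 1.68e-12 and 1.15e-12, 0.021 and 0.0199 estimated). All 23 Hox genes rose too (23 over the list alone, medians 3.26 and 3.08, 0.0282 and 0.0283 estimated). Epithelium genes rose in 11 of 15 in Arf-B and 14 in Arf-C with no falls (same over the list alone, medians 1.45 and 1.36, adjusted p = 6.38e-05 and 3.43e-06, 0.207 and 0.162 estimated). In Arf-B 5667 genes rose and 5809 fell, and in Arf-C 5636 and 5815. The share of calls that rose was 49.4% and 49.2%, against 63.7% and 61.7% when libraries are scaled to the same sum.

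At day 0 both Arf lines already differed from Ctrlv2 in many genes. Rhox5, an X-linked homeobox gene, was at 69.3 ± 9.78 FPKM in Ctrlv2 and at 0.338 ± 0.287 and 0.0708 ± 0.0802 in Arf-B and Arf-C (log2 -5.73 and -6.03, SE 0.19, adjusted p = 1.03e-11 and 5.86e-12). Stra8, a retinoic acid induced gene of meiosis, was lower at 1.54 ± 0.219 and 2.34 ± 0.353 against 41.9 ± 6.48 FPKM. Peg10, a paternally expressed imprinted gene, was at 0.402 ± 0.141 and 0.294 ± 0.0419 against 21 ± 2.04. S100a6, Rhox13, Fmr1nb, Pla2g7 and Pnma5 were the other large shared reductions (log2 from -4.57 for S100a6 in Arf-C to -2.78 for Pnma5 in Arf-B). Setbp1, which encodes a SET binding protein, was higher, at 13.1 ± 1.49 and 12.3 ± 2.28 against 0.187 ± 0.0251 FPKM (log2 3.57 and 3.47). Also higher was Cd24a, for a surface glycoprotein (31.8 ± 1.19 and 36.3 ± 1.78 against 6.65 ± 0.515). So were the transcription factor genes Zic2 (8.04 ± 0.867 and 7.17 ± 0.617 against 0.714 ± 0.19) and Tfap2c (11.9 ± 2.6 and 12.9 ± 0.893 against 1.95 ± 0.312). Mup6, Ripply1, the kinase gene Yes1 and the splicing kinase gene Clk1 were also higher in both (log2 1.77 for Clk1 in Arf-B to 2.21 for Mup6 in Arf-C). By the naming rule all 3 libraries of each Arf line lay on one side of all 3 of Ctrlv2 in each of these genes.

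Arf-B had 3277 genes higher and 3437 lower than Ctrlv2 at day 0, and Arf-C 3650 and 3706. By at least 2-fold 223 were higher and 447 lower in Arf-B, and 246 and 512 in Arf-C. Called in both with the same sign were 2821 higher and 2954 lower genes (166 and 391 by at least 2-fold), and 1 gene had opposite signs. Independent calls would share 695.4 and 740.6, and simulated unchanged lines shared a mean of 0. That 0 follows from the setting, since lines without change give almost no calls. It does not show what a control line that itself differs would bring. The covariance of the fold changes across genes was 0.196 against 0.0123 in the simulation (difference 0.184). The 3 Ctrlv2 libraries cannot be split, so part of the excess may come from the shared controls. Genes called in 1 line alone were fewer. Ddx3y, a gene of the Y chromosome, was at 0.554 ± 0.0984 FPKM in Arf-C and not called in Arf-B (8.87 ± 0.556 against 13.3 ± 7.42 in Ctrlv2), where it was called without replicate 1 of Ctrlv2 (adjusted p = 0.00188). Ripply3 and Id2 were higher in Arf-C (log2 1.53 and 1.10). In Arf-B they were at 0.33 and 0.25, and Id2 was called there without replicate 1 of Ctrlv2 (adjusted p = 0.0287).

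Of the lists at day 0, Trp53 targets had 16 of 30 genes higher and 5 lower in each Arf line (same over the list alone, medians 0.31 and 0.33, adjusted p = 0.0152 and 0.0377, 0.833 and 0.883 with an estimated correlation). Ccng1 was at 74.8 ± 12.7 and 77.2 ± 4.47 against 33.5 ± 3.42 FPKM. Trp53inp1 was at 36.9 ± 6.04 and 36.8 ± 1.07 against 17.4 ± 5.51. Perp (6.91 ± 0.493 and 6.6 ± 0.96 against 22.4 ± 2.53) and the proapoptotic gene Pmaip1 (8.91 ± 1.08 and 6.4 ± 0.607 against 27.8 ± 2.5) were lower. Primitive and parietal endoderm genes were lower in 9 and 10 of 15 and higher in 1 (same over the list alone, medians -0.52 and -0.47, adjusted p = 0.0152 and 0.0192, 0.833 and 0.822 estimated). The matrix gene Sparc was at 26.8 ± 2.92 and 24.8 ± 0.608 against 88.1 ± 7.88 FPKM. Hypoxia and glycolysis genes were lower in 4 and 9 of 19 tested identifiers, Aldoa counting with 2 identifiers (same over the list alone, medians -0.20 and -0.36, adjusted p = 0.0246 and 0.0109, 0.833 and 0.822 estimated). Hk2, a hexokinase gene, was at 32.9 ± 3.8 and 28.7 ± 3.71 against 87.7 ± 8.93 FPKM, and Slc2a1, a glucose transporter gene, at 33.2 ± 4.69 and 35.5 ± 1.04 against 90.2 ± 5.81. Stress and immediate early genes were lower in 7 of 14 in each line (7 over the list alone, medians -0.32 and -0.23, adjusted p = 0.0246 and 0.0377, 0.833 and 0.914 estimated). Egr1 was at 6.34 ± 0.511 and 3.28 ± 0.0321 against 20.9 ± 1.17 FPKM. Apoptosis regulators were lower in 10 of 20 and higher in 1 in each line (10 and 11 lower over the list alone, medians -0.19 and -0.23, adjusted p = 0.0478 and 0.0377, 0.833 and 0.822 estimated). Extracellular matrix genes were lower in 10 and 11 of 22 and higher in 1 (same over the list alone, medians -0.21 and -0.27, adjusted p = 0.0144 and 0.0157, 0.833 and 0.892 estimated). Formative and primed pluripotency genes were called in Arf-B alone (6 of 8 higher, 2 lower, same over the list alone, median 0.57, adjusted p = 0.0478, 0.833 estimated), with a similar median in Arf-C (0.55, adjusted p = 0.127). Otx2 was at 5.56 ± 0.629 and 5.84 ± 0.33 against 1.11 ± 0.124 FPKM. Germline genes were called in Arf-C alone (6 of 13 lower, 1 higher, same over the list alone, median -0.26, adjusted p = 0.0395, 0.822 estimated), with a similar median in Arf-B (-0.27, adjusted p = 0.143).

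At day 8 the Arf lines again differed from Ctrlv2 in many genes. Nanog was at 34.5 ± 9.98 FPKM in Arf-B and 32.9 ± 12.9 in Arf-C against 0.537 ± 0.478 (log2 4.55 and 4.44, SE 0.285, adjusted p = 2.04e-08 and 2.74e-08). Dppa5a, another gene of undifferentiated cells, was at 558 ± 89.1 and 536 ± 128 against 69 ± 10.6. Lama1, a laminin gene of basement membranes, was at 4.71 ± 0.814 and 4.82 ± 0.338 against 72.5 ± 18.3 FPKM (log2 -3.66 and -3.63). Srgn, a proteoglycan gene, was at 0.316 ± 0.0801 and 0.334 ± 0.261 against 12.1 ± 3.26. The imprinted gene Peg10 was lower (4.3 ± 0.348 and 14.5 ± 1.45 against 407 ± 45.7 FPKM, log2 -6.26 and -4.72, SE 0.0974, adjusted p = 7.58e-16 and 5.71e-14). So were Mest (1.34 ± 0.173 and 3.29 ± 0.346 against 53.8 ± 2.4) and Rhox5 (log2 -3.97 and -4.02). The tight junction gene Cldn3 (25 ± 2.49 and 26 ± 0.44 against 2.9 ± 0.513 FPKM), the water channel gene Aqp3 and the homeobox gene Cdx1 (15.9 ± 3.71 and 15.8 ± 3.08 against 1.9 ± 0.532) were higher. So were Fam25c, Ooep and the mitochondrial transfer RNA mt-Tv, a short gene with few reads. Pmel, Acta1 and Hmox1, the heme oxygenase gene, completed the shared reductions. Hmox1 varied widely in Ctrlv2 (363 ± 160.3 FPKM, against 50.3 ± 4.92 and 41.8 ± 11.6). The naming rule again demands that in each of these genes the 3 libraries of each Arf line lie apart from the 3 of Ctrlv2.

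Higher and lower than Ctrlv2 at day 8 were 2799 and 2908 genes in Arf-B, and 2890 and 2885 in Arf-C. By at least 2-fold they were 206 and 277 in Arf-B, and 193 and 299 in Arf-C. Both lines shared 2258 higher and 2446 lower genes (155 and 246 by at least 2-fold), and 1 gene had opposite signs. Independent calls would share 470.3 and 487.8, simulated unchanged lines a mean of 0.01, and the covariance was 0.161 against 0.0122 in the simulation (difference 0.149), again with shared Ctrlv2 libraries. As at day 0, the simulated count is near 0 by its setting. Higher genes made up 49% of the calls in Arf-B, 50% in Arf-C and 48% of the shared ones, against 69.5%, 64.4% and 66.3% when scaled to the same sum. Called in 1 line alone with the largest changes were mostly small RNA genes with few reads. Beyond these, Ubap2l was lower in Arf-B (13.1 ± 0.401 against 23.4 ± 1.32 FPKM in Ctrlv2 and 21.7 ± 0.626 in Arf-C). Atf3, a stress response factor gene, was lower in Arf-C (19.6 ± 1.77 against 35 ± 5.42; 25 ± 4.73 in Arf-B). In Arf-B Atf3 was called without replicate 1 of Ctrlv2 (adjusted p = 0.0342) or replicate 2 of Arf-B (0.0409).

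Naive pluripotency genes were higher at day 8 in 12 of 15 in each Arf line with none lower (13 over the list alone, medians 1.53 and 1.3, adjusted p = 3.69e-10 and 2.78e-10, 0.175 and 0.181 with an estimated correlation). Among them were Esrrb (15.6 ± 3.1 and 16.2 ± 4.68 against 2.77 ± 0.415 FPKM) and Nr0b1 (4.08 ± 1.45 and 3.98 ± 1.15 against 0.277 ± 0.253). Core pluripotency genes were higher in 7 of 11, with 0 lower in Arf-B and 1 in Arf-C (same over the list alone, medians 0.59 and 0.38, adjusted p = 0.000195 and 0.000871, 0.175 and 0.186 estimated). Pou5f1 was at 24 ± 3.36 and 17.5 ± 5.73 against 3.53 ± 0.57 FPKM and Sox2 at 52.3 ± 6.95 and 59.6 ± 14.3 against 25.1 ± 2.36. Primitive and parietal endoderm genes were lower in 14 of 15 in each (14 over the list alone, median -1.14 in both, adjusted p = 3.66e-15 and 9.85e-15, 0.0762 and 0.0845 estimated). Sparc was at 43.1 ± 2.0 and 42.7 ± 3.67 against 182 ± 21.7 FPKM and Col4a1 at 12.9 ± 1.1 and 15.7 ± 0.721 against 72.9 ± 11.8. Extracellular matrix genes were lower in 14 of 22 and higher in 2 (15 and 3 over the list alone in Arf-B, 14 and 2 in Arf-C, medians -0.53 in both, adjusted p = 1.66e-07 and 1.15e-07, 0.175 and 0.181 estimated). Stress and immediate early genes were lower in 12 and 13 of 14 (13 over the list alone in each, medians -0.72 and -0.89, adjusted p = 3.53e-07 and 1.45e-08, 0.175 and 0.181 estimated). Egr1 was at 8.14 ± 2.34 and 4.84 ± 1.51 against 40.4 ± 12.2 FPKM.

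Epithelium genes were higher in 11 of 15 and lower in 3 in each Arf line at day 8 (same over the list alone, medians 1.13 and 1.06, adjusted p = 1.33e-06 and 4e-06, 0.175 and 0.186 with an estimated correlation). The adhesion gene Epcam was at 91 ± 4.88 and 86.8 ± 4.39 against 23.1 ± 2.49 FPKM, and Krt8 was lower at 56.6 ± 11.3 and 53 ± 13.4 against 165 ± 13.5. Mesenchyme and fibroblast genes were lower in 7 and 8 of 13 and higher in 2 (same over the list alone, medians -0.33 and -0.60, adjusted p = 0.0137 and 0.00513, 0.175 and 0.181 estimated). Acta2, for smooth muscle actin, was at 1.62 ± 0.283 and 1.36 ± 0.41 against 15.8 ± 4.53 FPKM. Hox genes were higher in 17 and 16 of 23 and lower in 3 and 4 (same over the list alone, medians 0.62 and 0.54, adjusted p = 1.28e-06 and 1.62e-05, 0.175 and 0.181 estimated). Hoxc8 was at 8.21 ± 0.445 and 7.49 ± 1.15 against 2.6 ± 0.229 FPKM. Wnt targets were higher in 6 and 7 of 11 and lower in 1 (8 and 7 higher over the list alone, medians 0.31 in both, adjusted p = 0.00366 and 0.00434, 0.0912 and 0.0999 estimated). Axin2, a feedback target of the pathway, was at 4.93 ± 0.441 and 5.09 ± 0.157 against 1.65 ± 0.0821 FPKM. Replication-dependent histones were higher in 6 and 5 of 8 (same over the list alone, medians 0.53 and 0.52, adjusted p = 0.00196 and 0.0128, 0.154 and 0.181 estimated). Polyadenylated RNA holds few of their transcripts. Imprinted genes were lower in 9 of 21 with 5 and 4 higher (9 and 10 lower, 5 higher over the list alone, medians -0.18 and -0.23, adjusted p = 0.0137 and 0.00434, 0.175 and 0.158 estimated). Nodal and activin targets were called in Arf-C alone (7 of 11 lower, 2 higher, 8 and 2 over the list alone, median -0.57, adjusted p = 0.00513, 0.181 estimated). Skil was at 21 ± 0.126 against 35.1 ± 2.02 FPKM. Of the endoderm genes, Gata4, in the chromosome 14 segment (6.39 ± 0.309 and 7.0 ± 0.499 against 25.1 ± 1.69 FPKM), and Gata6 (2.27 ± 0.291 and 2.68 ± 0.0503 against 6.47 ± 0.814) were lower. Foxa1 was higher (log2 1.33 and 1.37). Among pancreas genes Dlk1 (23.8 ± 3.04 and 20.2 ± 5.54 against 13.6 ± 2.44) and Pax6 (2.71 ± 0.404 and 2.16 ± 0.423 against 0.891 ± 0.0555) were higher. For Dlk1 the call in Arf-C was lost without replicate 2 of Ctrlv2 (adjusted p = 0.0876) or replicate 1 of Arf-C (0.0877). Prox1 (1.3 ± 0.0917 and 1.36 ± 0.245 against 2.89 ± 0.241) was lower. Ins2, the insulin gene, was listed at 0 in Ctrlv2 and at 0.489 ± 0.14 and 0.477 ± 0.136 FPKM in the Arf lines, an abundance of few reads. The lists of these genes were not called in either line: endocrine pancreas (8 of 22 tested, adjusted p = 0.215 and 0.305), pancreatic progenitor (medians -0.07 and -0.00464, 0.913 and 0.958) and definitive endoderm (medians -0.14 in both, 0.38 and 0.484).

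**Figure D3:**
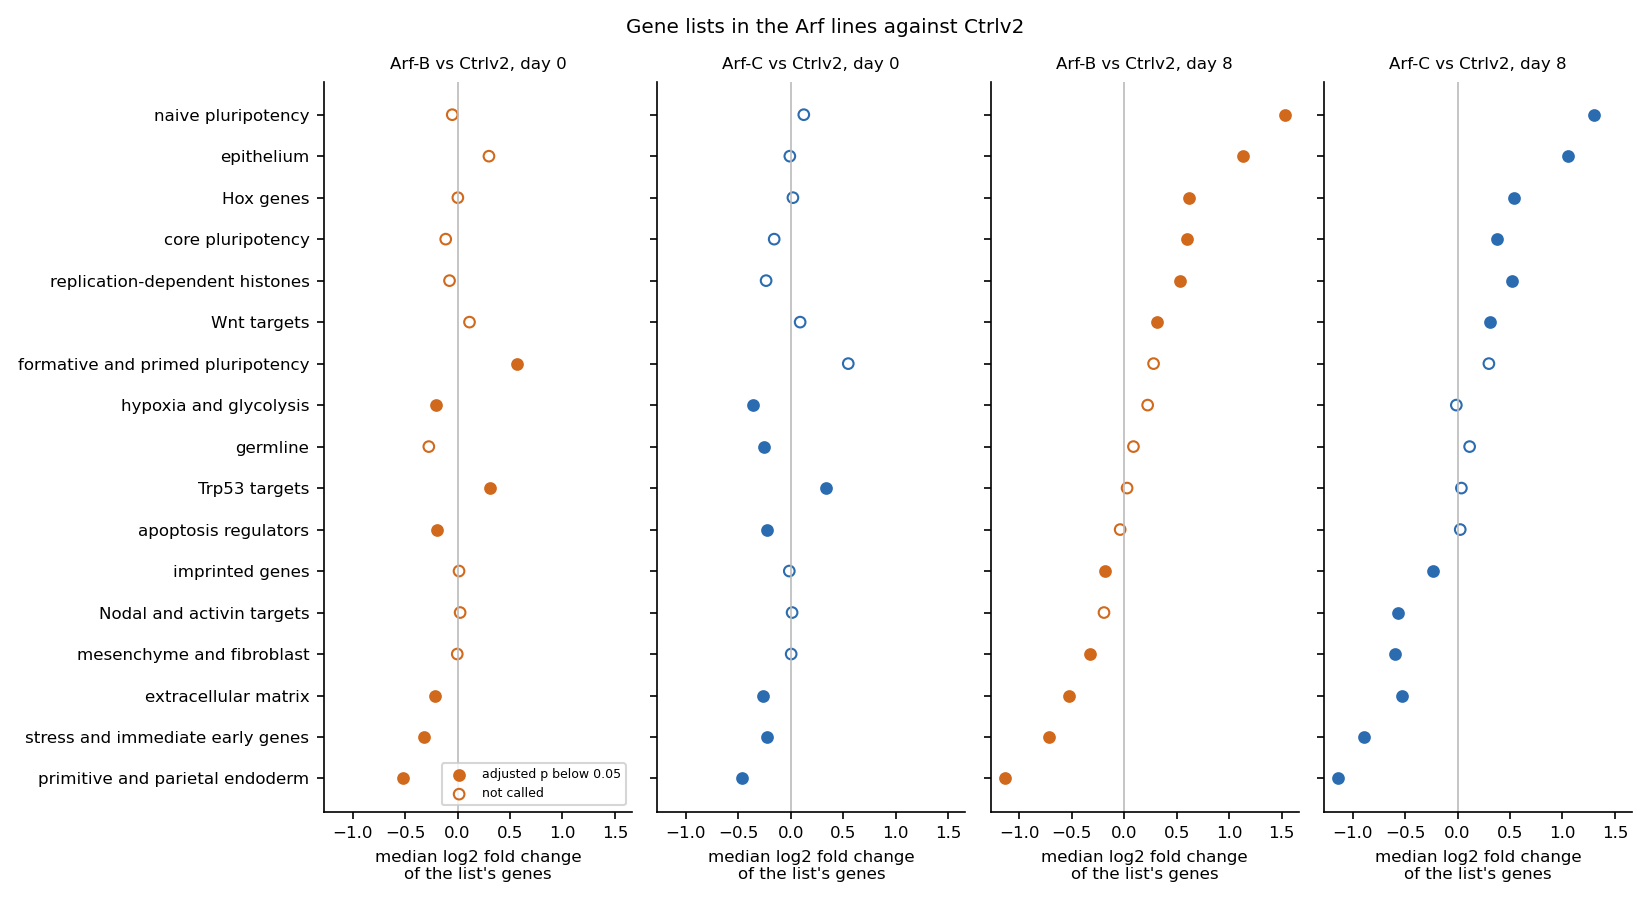
Median log2 fold change of 17 gene lists in each Arf line against Ctrlv2 at day 0 and day 8, with filled points for lists called at an adjusted p below 0.05 with the preset correlation. Naive pluripotency is near 0 at day 0 and at 1.53 (Arf-B) and 1.3 (Arf-C) at day 8, and primitive and parietal endoderm is lower at both days.

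The day response itself differed between each Arf line and Ctrlv2, tested as an interaction. Fbxo2, which encodes a subunit of a ubiquitin ligase, went from 56.5 ± 3.14 to 26.7 ± 0.631 FPKM in Ctrlv2. It went from 11.3 ± 1.45 to 58.9 ± 3.64 in Arf-B and 9.23 ± 0.749 to 61.5 ± 7.88 in Arf-C (difference in log2 fold change 3.34 and 3.66, SE 0.131, adjusted p = 5.08e-10 and 1.46e-10). Stra8 went from 41.9 ± 6.48 to 807 ± 46.1 FPKM in Ctrlv2. It went from 1.54 ± 0.219 to 668 ± 15.1 in Arf-B and from 2.34 ± 0.353 to 707 ± 30.1 in Arf-C (differences 3.80 and 3.49). Pmel, a melanosome protein gene, went from 17.7 ± 2.79 to 26.7 ± 1.12 FPKM in Ctrlv2. It went from 24.7 ± 0.745 to 2.76 ± 0.32 and 33.2 ± 1.04 to 1.84 ± 0.418 in the Arf lines (differences -3.36 and -4.18). Nanog, S100a6 and Rhox13 had the other large positive differences and Setbp1, Hmox1, Acta1 and, in the chromosome 14 segment, Stmn4 the other negative ones. The interaction called 3007 genes with a more positive and 2763 with a more negative response in Arf-B (589 and 389 by at least 2-fold) and 3337 and 3255 in Arf-C (647 and 509). In Arf-B 52.1% of the called genes were more positive, against 66% when libraries are scaled to the same sum. Of the lists 11 and 13 were called and none holds with an estimated correlation (adjusted p of at least 0.163 and 0.266). Of the 6 preset genes, Cdkn2a (0.66 and 0.57) and Trp53 (0.58 and 0.43) had more positive responses in both lines and Mdm2 (-0.87 and -0.91) more negative ones. With thinned reads Cdkn2a was called in neither (adjusted p = 0.178 and 0.304). Cdkn1a was called in Arf-C (-0.71, adjusted p = 0.00566) and in Arf-B only without replicate 1 of Ctrlv2 at day 0 (0.0222). Npm1 and Cdkn2b were not called. In Arf-B Npm1 was called without replicate 2 of Ctrlv2 (0.0265) or replicate 1 of Arf-B (0.0325) at day 0, and Cdkn2b without replicate 1 of Ctrlv2 at day 8 (0.0462).

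Arf-B and Arf-C differed from each other in few genes. At day 0 Ddx3y was higher in Arf-B (8.87 ± 0.556 against 0.554 ± 0.0984 FPKM, log2 2.67, SE 0.249, adjusted p = 0.000147). So were Platr14 and the DNA methyltransferase gene Dnmt3b (19.7 ± 3.12 against 13.8 ± 0.226). Ripply3 (11.4 ± 2.01 against 27.3 ± 1.07), Slc9a3r2 and Trpm1 were lower. The Dnmt3b call was lost without replicate 3 of Arf-B (adjusted p = 0.0515) or replicate 1 or 3 of Arf-C (0.085 and 0.0807). None of the 6 preset genes was called between the 2 lines at either day. At day 8 Peg10 was lower in Arf-B (4.3 ± 0.348 against 14.5 ± 1.45 FPKM, log2 -1.54, SE 0.0974, adjusted p = 1.08e-06), as was Ubap2l. The linker histone gene Hist1h1c was higher (18.4 ± 1.71 against 11.8 ± 0.906). Without replicate 1 of Arf-B neither Ubap2l (adjusted p = 0.0513) nor Hist1h1c (0.132) was called, and the Hist1h1c call was lost with each of 5 libraries left out alone. The limma test called 18 genes higher and 41 lower in Arf-B at day 0 and 6 and 4 at day 8 (1894 and 912 at an unadjusted p below 0.05). The 59 calls of day 0 rest on single libraries, ranging from 18 without replicate 3 of either line to 69 without replicate 2 of Arf-C. They also depend on the method: a fit of these groups alone called 7 at day 0 and 5 at day 8, and limma-voom, chosen after seeing the data, 168 at day 0. Another split of the same 6 libraries called 68 at day 0. Nodal and activin targets were higher in Arf-B at day 8 (2 of 11 called, 4 over the list alone, median 0.15, adjusted p = 5.8e-09, 0.00839 with an estimated correlation). The called members were Lefty1 (4.99 ± 1.59 against 1.17 ± 0.135 FPKM) and Lefty2 (2.29 ± 0.827 against 0.267 ± 0.26), which encode Nodal inhibitors. Of 3 other lists called at day 8 and 4 at day 0 no member was called by limma over all genes (over the list alone 4 epithelium, 4 germline and 3 ribosome biogenesis genes at day 0). None holds with an estimated correlation (adjusted p of at least 0.655 and 0.709).

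Chromosome medians moved most on chromosome 14, by -0.17 and -0.16 log2 at day 0 and -0.21 and -0.20 at day 8 in Arf-B and Arf-C against Ctrlv2 (465 genes, SE 0.0148, adjusted p = 4.67e-09, 1.01e-08, 1.67e-10 and 1.67e-10). Called were 9, 10, 6 and 5 of 20 chromosomes for Arf-B and Arf-C at day 0 and at day 8, the largest positive median being 0.14 on chromosome X in Arf-B at day 0. Along chromosomes, windows chosen after seeing the data show where the lower genes lie. From 60 to 80 Mb of chromosome 14 the median gene of 100 was at a ratio of 0.502 and 0.505 to Ctrlv2 at day 0 and 0.521 at day 8 in both Arf lines (89% to 94% of genes lower, against 48.9% in the rest of the genome). From 115 to 145 Mb of chromosome 2 the median of 169 genes was at 0.7 to 0.705 (86.4% to 88.2% lower). Of the genes the rule takes 17 lie there: Gata4, Sox7, Tdh, Stmn4, Nefl and Piwil2 on chromosome 14, and Meis2, Bmf, Chac1, B2m, Fbn1, Bcl2l11, Polr1b, Nop56, Pcna, Platr3 and Jag1 on chromosome 2. Not all follow the segments. Tdh, Nefl and Meis2 were called lower than Ctrlv2 in neither line at either day, Gata4 was not called at day 0 (1.57 ± 0.276 and 2.0 ± 0.331 against 1.72 ± 0.282 FPKM), and B2m was higher in Arf-C at day 0 (47.7 ± 4.14 against 34 ± 2.74). Jag1, a Notch ligand gene higher at day 0 (5.16 ± 0.111 and 4.5 ± 0.331 against 1.74 ± 0.089), and Platr3 lie in a part of the chromosome 2 segment with too few genes to be tested. Without the genes of these segments, an alternative also chosen after seeing the data, 5522 of 16778 genes at day 0 and 4422 at day 8 were called in both Arf lines with the same sign.

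**Figure D4:**
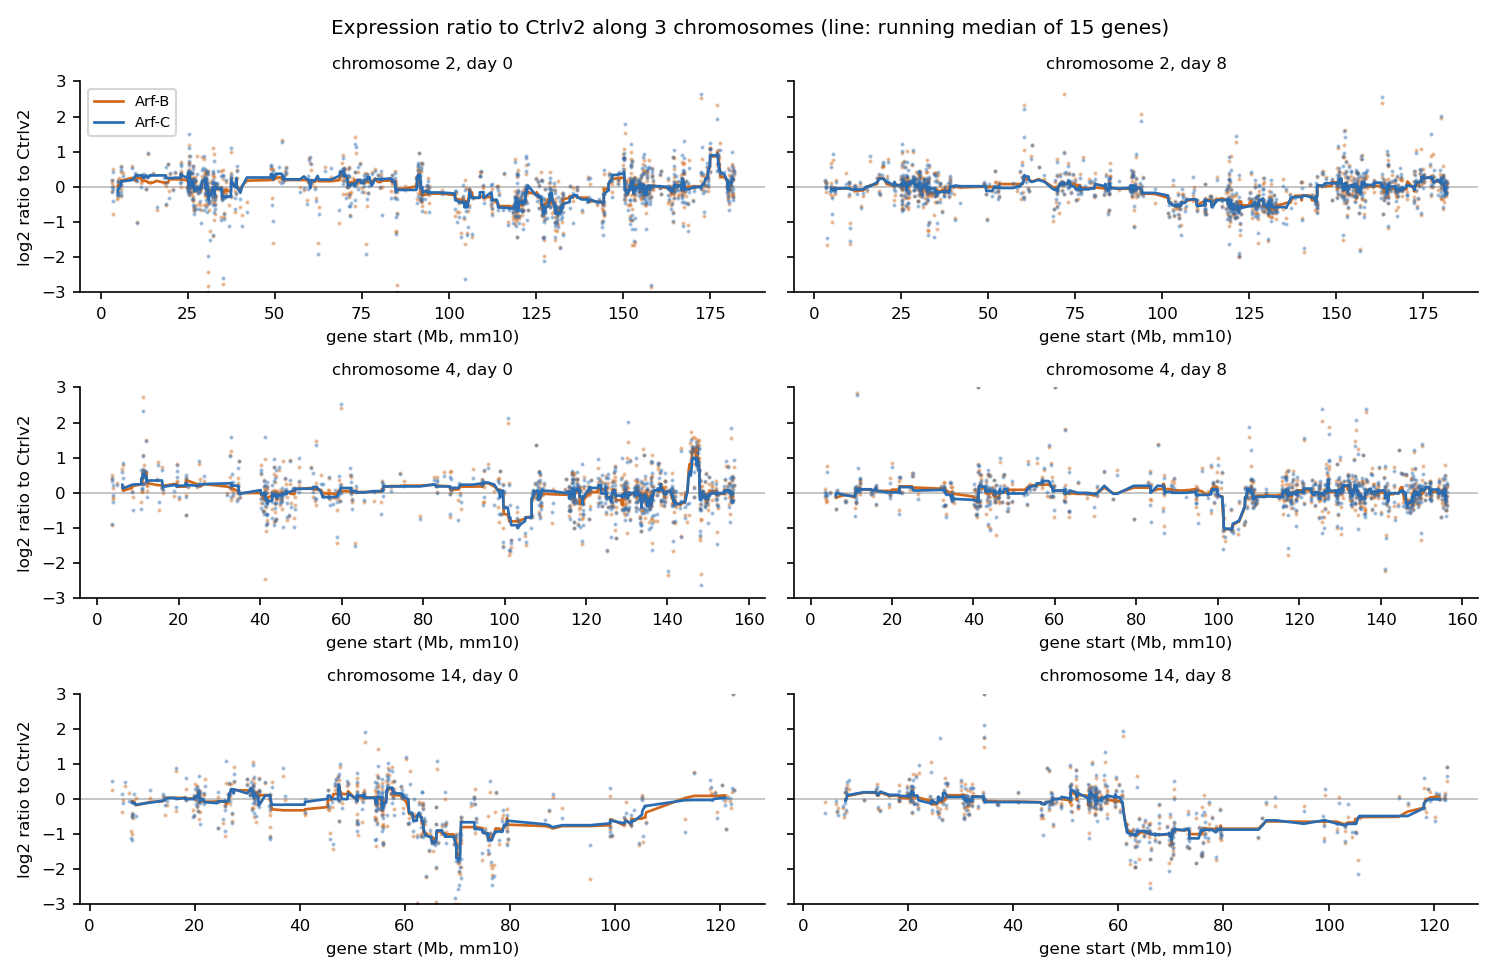
Log2 ratio of each Arf line to Ctrlv2 (drawn within 3 of 0) for genes along chromosomes 2, 4 and 14 (gene start in Mb), with 1 point per gene and a line at the running median over 15 genes. The ratios are lower between 100 and 105 and between 115 and 145 Mb of chromosome 2, between 100 and 105 Mb of chromosome 4 and between 60 and 80 Mb of chromosome 14.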

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

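Chosen only after the results were seen were the tests of depth, of the chromosome segments and of the single control line for the first pattern, and all tests of the second; the counts of splits were planned.

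The day response differed between the Arf lines and Ctrlv2 by the interaction test, in 5770 genes for Arf-B and 6592 for Arf-C. In 100 drawn splits of the line labels within each day, 2 gave as many genes in each case, the real one included (highest other 7261 and 7405). These splits cannot test the difference in day response. All but 2 mix libraries of lines that differ within a day, which widens the spread and lowers the count (at most 3089 and 3511). The split above the real count keeps the libraries of a line together within each day, which points to a structure of the samples: whole lines differ at each day.

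Differences between the day responses of Arf-B and Arf-C and that of Ctrlv2, on the log2 scale, were 4.55 and 4.14 for Nanog, 3.63 and 4.26 for S100a6, 3.80 and 3.49 for Stra8, 3.34 and 3.66 for Fbxo2, and 3.49 and 3.20 for Rhox13. They were -3.36 and -4.18 for Pmel, -3.17 and -3.23 for Setbp1, -3.02 and -3.39 for Hmox1, -2.82 and -2.94 for Acta1, and -2.70 and -2.93 for Stmn4, which lies in the chromosome 14 segment.

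Lists with such a difference in both lines, given as medians for Arf-B and Arf-C, were naive pluripotency (1.59 and 1.22), core pluripotency (0.71 and 0.40), epithelium (0.45 and 0.40), retinoic acid response (0.76 and 0.64), Hox genes (0.70 and 0.52), hypoxia and glycolysis (0.48 and 0.48) and replication-dependent histones (0.80 and 0.71). More negative were primitive and parietal endoderm (-0.81 and -0.69), mesenchyme and fibroblast (-0.59 and -0.79), imprinted genes (-0.47 and -0.59) and extracellular matrix (-0.38 and -0.29). None of these holds with an estimated correlation (adjusted p of at least 0.163 and 0.266).

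Arf-B and Arf-C differ from Ctrlv2 in many genes and from each other in few. Library depth as the cause is argued against by 4080 genes called in both lines at day 8 when all libraries are thinned to the smallest. Of the genes outside the chromosome segments at least 32.4% were called in each comparison, so their own dose in the segments cannot be the direct cause. Whether changed dose in the segments acts on genes elsewhere was not tested, so the segments as the whole cause stay open. A property of the single control line or of a shared origin of the Arf lines, and not of Arf, cannot be told apart from an effect of Arf, since the number of control lines is 1; the change named in the line labels stays open, as untested. Drawn splits of the 9 libraries of a day into 3 groups gave as many genes called in both lines in 3 of 100 at day 0 (5775, highest other 5811) and 1 of 100 at day 8 (4704, highest other 4668). The high splits keep the 3 Ctrlv2 libraries together. All others mix Ctrlv2 with Arf libraries, which widens the spread and lowers the count (at most 40 and 3). The splits therefore show only that the Ctrlv2 libraries lie apart from the Arf libraries at each day. What another control line would bring they cannot show.

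Naive pluripotency genes were higher at day 8 in both Arf lines (12 of 15 in each), a list call that is lost with an estimated correlation (adjusted p = 0.175 and 0.181). A higher level carried over from day 0 is argued against by a median log2 difference of 0.154 there, and depth by all 12 members called higher in both lines with thinned libraries. A residual share of cells that kept the whole day 0 profile would bring every gene abundant at day 0 to its level. In both lines 5 other such genes, Tdgf1, Txnip, Tdh, Tdgf1-ps1 and Gm46332, stay far below it. They were taken for lying low among 21 genes lost by Ctrlv2 in Arf-B and 20 in Arf-C. The level is a median over naive members that range from 1.22% to 20.1% in Arf-B and from 0.881% to 19.4% in Arf-C. These 5 genes therefore show only that they did not keep such a share themselves. Nr0b1 and Tcl1 kept at most 2.62% of their day 0 level, but these genes were picked for lying low. Their values therefore cannot test such a share. A share of cells that kept most of the day 0 profile may explain the rest. The share needed is 7.46% in Arf-B and 7.19% in Arf-C, after subtraction of the Ctrlv2 level at day 8. Without that subtraction, 23.8% of the other day 0 genes lie far below its level (under 0.5 of it) in the line with fewer. With it more do, such as Hsd17b14 (3.6%), Laptm5 (1.45%) and Triml1 (2.99%) in Arf-B. Such a share stays open beside a low level in many cells, which bulk RNA does not separate.

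For comparisons of 3 libraries with 3 the 10 splits are too few for a share under 0.05. As many genes as the real split were called in 1 of 10 for day 8 against day 0 in Ctrlv2 (11752, highest other 1), Arf-B (11476, highest other 2) and Arf-C (11451, highest other 1). The same held against Ctrlv2 for Arf-B and Arf-C at day 0 (6714 and 7356, highest others 0 and 8) and at day 8 (5707 and 5775, highest others 5 and 8). For Arf-B against Arf-C it was 2 of 10 at day 0 (59, highest other 68) and 1 of 10 at day 8 (10, highest other 5).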

How the results depend on the processing

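The fit by limma-voom, the thinned reads and the fit without segment genes were chosen after seeing the data. Outside the alternatives named next, every count of genes stayed within 1.5 times its value under the planned and added alternatives.

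With an absolute log2 fold change of at least 1 the counts fell by construction, to 3506 (Ctrlv2), 3006 (Arf-B) and 2947 (Arf-C) for the day response, 670 and 758 for Arf-B and Arf-C against Ctrlv2 at day 0, 483 and 492 at day 8, 557 and 401 in both lines, 978 and 1156 for the difference in day response, and 8 between the Arf lines at day 0. Arf-B against Arf-C gave 7 genes at day 0 and 5 at day 8 with these groups alone, 26 at day 8 without a filter, 20 at day 8 scaled to the same sum, and 168 at day 0 with limma-voom; the cause was not tested. Leaving out 1 library took its day 0 count from 18 (without Arf-B replicate 3) to 69 (without Arf-C replicate 2).

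Of 129 list calls over the comparisons 15 hold with an estimated correlation, which widens each test where members vary together. Chromosome medians called went from 30 to 17 with a mean of at least 10 FPKM; the cause was not tested. Scaled to the same sum, the median log2 fold change of all tested genes (21471, against 17200) was 0.163 and 0.147 for the day response of Arf-B and Arf-C (against -0.0217 and -0.0219), 0.116 for Arf-B at day 8 (against 0.0111) and 0.101 for its difference in day response (against 0.00507). More genes passed the same filter there, so this scaling also raises values against the fixed pseudocount of 1. That effect was not separated from the one of the library sums. Medians of called lists kept their sign, but several printed ones moved by more than 1.5 times under that scaling. Against Ctrlv2 at day 0 these were formative and primed pluripotency in Arf-B (0.93) and extracellular matrix (-0.386 in Arf-B, -0.447 in Arf-C); at day 8, Wnt targets (0.547 and 0.623), naive pluripotency in Arf-C (2.09), histones in Arf-B (0.923) and imprinted genes in Arf-B (-0.11). For the day response they were pancreatic progenitor (2.3), posterior foregut and gut tube (1.9) and trophoblast (1.74) in Ctrlv2 and Hox genes in Arf-C (4.67), and for the difference in day response extracellular matrix in Arf-B (-0.242). Printed medians of lists not called moved too. Definitive endoderm went to 1.52 for the day response of Ctrlv2 and to -0.072 in Arf-B at day 8. Pancreatic progenitor at day 8 changed sign, to 0.0123 in Arf-B and 0.0525 in Arf-C.

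Single genes reversed in the difference in day response alone. Peg10 in Arf-C went to 0.94 with a pseudocount of 0.1, 0.33 scaled to the same sum and 1.35 with limma-voom. Its FPKM rose from 0.294 ± 0.0419 to 14.5 ± 1.45 in Arf-C and from 21 ± 2.04 to 407 ± 45.7 in Ctrlv2. A pseudocount of 1 shrinks the rise from so low a level in Arf-C, so the sign of the main value rests on it. With limma-voom the value was 0.17 for Otx2, -0.16 for Hnf4a, -0.47 for Zic1, -0.0143 for Msx1, -1.75 for Hoxb1, 1.53 for Col6a1 and 0.41 for Egr2 in Arf-C, and 0.11 for Gata6, -1.38 for Hnf4a, -0.40 for Mnx1, 0.43 for Foxc1, 0.51 for Kdr, -1.07 for Hoxb1 and 2.56 for Col6a1 in Arf-B. For the genes other than Peg10 the cause was not tested. Of 1241 values of named genes limma-voom kept the call and sign of 1126, and of 9462 with 1 library left out 9026 were kept, 399 lost the call, 37 gained it and 0 reversed.

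The replicate number as a block kept 1221 of 1241 values, lost 15 and gained 5. Correlations of residuals from the group means, between libraries with the same number, averaged 0.00582 over 45 pairs (-0.251 to 0.203) against -0.00289 for other pairs, and 8 of 18 libraries correlated best with their own number.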

Other observations

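The windows along chromosomes were chosen after seeing the data. The tests on genes they left out were written before those genes were examined by themselves. Those genes are not independent data: they come from the same libraries and were part of the chromosome medians.

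Expression of neighbouring genes is lower in both Arf lines along parts of chromosomes 2 and 14. A change of gene dose may lie behind this: in genes the windows did not use (mean of 1 to 3 FPKM) the median log2 ratio nearest to 0 was -0.335 over 35 genes on chromosome 2 and -0.972 over 28 on chromosome 14. The median farthest from 0 was -0.497 on chromosome 2 (Arf-B at day 8) and -1.47 on chromosome 14 (Arf-B at day 0). For reference, 1 copy over 2 would give -1 and 2 over 3 would give -0.585. At least 82.5% of these 63 genes were lower in each comparison (96.4% on chromosome 14, 71.4% to 85.7% on chromosome 2, with upper quartiles above 0 there at day 8, 0.0891 and 0.139). A few strongly lower genes cannot pull a median, so this share is no separate test of that explanation. Expression ratios give no copy number, so which side changed stays open.

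Of 11 windows called 2 stand alone. On chromosome 2, from 100 to 105 Mb, the medians of Arf-B and Arf-C over 18 genes were -0.422 and -0.445 at day 0 and -0.582 and -0.542 at day 8, and the windows from there to 115 Mb were lower without being called (-0.126 to -0.467). On chromosome 14 no window from 80 to 100 Mb had enough genes, and the one from 100 to 105 Mb was lower without being called (medians from -0.577 to -0.812 over 8 genes), so the end of that stretch is not shown. The window of chromosome 4, from 100 to 105 Mb, was lower, with medians over 12 genes of -0.807 and -0.866 at day 0 in Arf-B and Arf-C and of -1.03 at day 8 in Arf-C (permutation p = 1e-04, the smallest they can give). Jak1, which encodes a kinase of cytokine receptors, lies there, at 7.85 ± 0.379 and 8.86 ± 1.33 against 26.9 ± 1.08 FPKM at day 0. At day 8 its log2 fold change was -1.03 in Arf-B (adjusted p = 1.88e-07). Leprot was at 29.4 ± 1.94 and 27.7 ± 1.01 against 74 ± 3.15 and Ak4 at 8.17 ± 0.108 and 8.57 ± 0.976 against 26.1 ± 0.849 at day 0. Ssbp3, beyond the window, was not called (log2 -0.01 and 0.08 at day 0).

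Beside Peg10 on chromosome 6, Sgce, imprinted from the same promoter region, was at 0.0272 ± 0.0174 and 0.119 ± 0.0308 against 4.82 ± 0.0834 FPKM at day 8, while the neighbour Casd1 was at 14.8 ± 0.576 and 13.6 ± 0.535 against 15.7 ± 0.891 and Ppp1r9a at 6.85 ± 0.446 and 6.64 ± 0.412 against 4.21 ± 0.639. Uty, of the Y chromosome like Ddx3y, was at 0.096 ± 0.0424 FPKM in Arf-C at day 0 against 2.98 ± 0.362 in Arf-B and 2.73 ± 0.813 in Ctrlv2, and has an X-linked paralog. Eif2s3y, also Y-linked, was reduced less in Arf-C, to 9.75 ± 0.757 against 17.3 ± 3.53 FPKM at day 0, and at day 8 was at 9.5 ± 0.686 in Arf-B and 8.42 ± 1.02 in Arf-C against 19.6 ± 1.48. In Arf-B Uty was not called at day 0. At day 8 Uty and Ddx3y were lower in each Arf line too, Uty at 2.16 ± 0.212 and 0.0462 ± 0.0379 against 6.64 ± 0.552 and Ddx3y at 3.88 ± 0.538 and 0.24 ± 0.105 against 19.8 ± 1.09 FPKM.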
